A study of Mus musculus with 2 samples.

How the data were processed

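DNase-seq was analysed from 2 libraries of tissue labelled layer of hippocampus, of B6CASTF1/J mice, 25 days old and labelled male. They were taken as biological replicates 1 and 2 of 1 group as the labels number them. For each library the deposited files gave narrow peaks, a shorter list of narrow peaks, footprints and runs of bases with an FDR. Per the file headers and the list of files that came with each library, the assembly was mm10 and all lists were made from that library's own alignments, so that replicates were not pooled. The aligner, the peak and footprint callers, their versions and their filters are not given in the sources used here.

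The peak value is the authors' signal, the height of a coverage-like track per library, and its scaling is not given in the sources used here. All values were whole multiples of 1 step, 0.00707 in replicate 1 and 0.00645 in replicate 2, within 2% of a step. What 1 step stands for is not stated, so the number of cuts in each library and behind each peak is unknown. The p-value type column is the authors' FDR per run of bases, and the deposited files list bases with an FDR under 0.05. Every peak of the main list held a base with an FDR under 0.05, and every peak of the shorter list one of at most 0.001, checked on the files. The footprint files carry a constant value in that column, which was not used. Peak values served to describe and rank peaks within a library, and values of both libraries were set side by side as given by the authors. Comparisons of the libraries placed lists of genes among random lists and did not test 1 library against the other.

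Genes, exons and transcription start sites (TSS) were taken from GENCODE M21 and sequence from GRCm38.p6, the same build as mm10. Overlaps were made with bedtools 2.31.1 and with interval code in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), figures with matplotlib 3.10.9, and searches for sequence copies with blastn 2.17.0 (at least 90% identity over at least 80% of the length). Peaks were shared when they overlapped by at least 1 bp. Intervals on shares are exact (Clopper-Pearson, 95%) and cover counting error only. Chance overlap came from 100 draws of the peaks moved on their chromosome, or of footprints moved to random places among all peaks of replicate 2. A promoter peak overlapped the window of 1 kb on each side of an annotated TSS of a protein-coding gene, and a distal peak overlapped no such window.

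Distal peaks were counted in each gene extended by 10 kb at both ends, and each count was given as a percentile among the 200 genes nearest in length. The mean percentile of a list, and the share of its genes with a promoter peak in both libraries, were compared with 10000 random lists of the same size (two-sided, smallest p 0.0002), with Benjamini-Hochberg adjustment over the 28 lists at 0.05. The difference between libraries was log2 of the summed peak value plus 0.5 over the extended gene, replicate 1 minus replicate 2, less the median over 18050 genes, and the list median was placed among 10000 random lists matched on mean summed value in 20 bins. For 24 motifs written as consensus sequences, sites in peaks whose middle base lay in a footprint were compared with the motif written in reverse order by Fisher's exact test in each library, with Benjamini-Hochberg adjustment over motifs; a motif was called when both libraries passed in the same direction. The X to autosome ratio used median peak values.

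The lists covered dentate gyrus granule cells, CA1, CA2 and CA3 pyramidal cells, excitatory, inhibitory and all neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, ependymal and choroid plexus cells, meningeal fibroblasts, neural progenitors and immature neurons, other brain regions, erythroid cells, lymphocytes, liver, skeletal muscle and heart, germ line, and activity-regulated, housekeeping, glutamate receptor, GABA receptor, imprinted, HOX and olfactory receptor genes. Grik4, Grin2a and Grin2b stand in more than 1 list. Lists, motifs, tests, the rule for named genes and most alternatives were fixed before the data were examined. That rule names, for each list, the 2 genes with the highest and the 1 with the lowest distal percentile, 15 genes chosen in advance, the 10 genes with the most distal peaks, the 10 strongest shared peaks and the 5 strongest peaks of each library without a partner; other genes were chosen after their values were seen. Names of genes that lie in dense runs and of sex-linked genes other than Xist are of that kind.

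The tests were tested on simulated data. With 3-fold more distal peaks, 20 of 20 lists of 14 genes among 21755 genes were called and 0 of 20 unchanged lists. Of lists of 14 genes with changed promoter peaks 18 of 20 were called and 1 of 20 unchanged lists. Of motifs with 1500 sites 12 of 12 changed and 0 of 12 unchanged were called. The simulated drop in promoter peaks was large, and the simulated motifs had many backward sites. Power for shorter lists, smaller shifts or motifs with few backward sites was not simulated.

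Alternatives were a reciprocal overlap of 50%, equal numbers of peaks, the FDR of 0.001, regions with an FDR under 0.05 in place of peaks, TSS windows of 500 bp and 2.5 kb, all annotated genes, gene bodies alone, extensions of 50 kb, the 100 nearest genes, random lists matched on CpG, peak numbers in place of values, mean in place of median values, whole motifs, distal peaks, the share of peak bases in footprints as reference, and leaving out each library. Chosen after seeing the data were an analysis without peaks that touch a dense run, at least 12 peaks called in 1 library alone that follow each other with gaps of at most 6 kb, and analyses of autosomes alone. The 183 protein-coding genes on Y were left out of the list tests. Ahsp had no match in the annotation, and H19, Meg3, Kcnq1ot1 and Airn are not protein-coding and were left out of the imprinted list.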

Results

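DNase I cuts DNA most often where chromatin is open, so DNase-seq finds promoters, enhancers and other regulatory regions as peaks of cuts and bases shielded by a bound protein as short footprints inside them. The data are 2 DNase-seq libraries of tissue labelled layer of hippocampus, from B6CASTF1/J mice, a hybrid of a laboratory strain and the wild-derived CAST strain. The hippocampus is the brain structure that holds the dentate gyrus and the CA fields, and the labels do not name the layer. Both were labelled male and 25 days old, and they form 1 group, biological replicates 1 and 2. The labels name separate tissue samples under a shared donor entry, so whether they came from separate animals is not known, and the spread between them may be technical. Peaks at sex-linked genes went against the male label of replicate 2, and that library is called the library labelled male replicate 2 where a direction between the libraries is drawn. Replicate 1 had 93545 peaks over 23.3 Mb and the library labelled male replicate 2 had 79144 over 18.0 Mb, a mean of 86344.5 ± 10183 (SD, n = 2), with 223251 and 170016 footprints. Positions are in mm10. With a single group the data allow no comparison of conditions, and the comparisons concern the replicates, the places where peaks lie, gene groups, footprints and the X chromosome.

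The first question was whether the same places were open in both libraries. With peaks classed by their middle base, those at promoters were shared most often. Of these, 78.3% in replicate 1 and 85.1% in replicate 2 overlapped a peak of the other library. The shares were 47.4% and 62.2% for peaks in introns of protein-coding genes and 56.0% and 66.0% for intergenic peaks. The strongest shared peak lay on chromosome 17 from 39846781 to 39846920, inside the gene CT010467.1, with peak values of 76.6 and 69.0. Next came a peak in the UTR of Lars2, the mitochondrial leucyl-tRNA synthetase (chromosome 9 from 123461881 to 123462140, 37.7 and 36.5), and one in an intron of Zc3h7a that also overlaps the annotated gene Gm23935 (chromosome 16 from 11144171 to 11144320, 31.4 and 31.0). Of the remaining peaks among the 10 strongest, a pair lay between genes, on chromosome 3 from 5860361 to 5860530 (mean value 31.1) and on chromosome 6 from 49236421 to 49236640 (25.7). The others lay in introns of Il31ra (27.2), Kpna1 (20.7) and Gphn (13.6), in the UTR of Cers5 (24.9) and inside Gm10060 (13.99). Near-identical sequence occurred elsewhere in the reference for several of them, which limits how firmly those values belong to these places. There was 1 other copy of the CT010467.1 peak, 6 of the Zc3h7a peak, 15 of the chromosome 3 peak, 8 of the Il31ra peak and 6 of the Gm10060 peak. Copies that the reference lacks could not be counted.

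In all, 59.8% of the peaks of replicate 1 (95% exact interval 59.5 to 60.1) and 71.7% of those of replicate 2 (71.4 to 72.0) overlapped by at least 1 bp, 65.2% of both lists together. Peaks moved to random places on the same chromosomes overlapped in 1.66% ± 0.05 (SD of 100 draws). Sharing rose with the peak value, from 8.94% and 22.3% of the weakest 10% of each list to 99.0% and 99.5% of the strongest 10%. Over 44793 regions with 1 peak in each library, the peak values had Spearman's rho of 0.921 and Pearson's r of 0.931 on the log2 scale, and 98.7% lay within 2-fold. These correlations are across regions, which are not replicates. With a reciprocal overlap of at least 50%, 42.7% of both lists were shared.

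**Figure D1:**
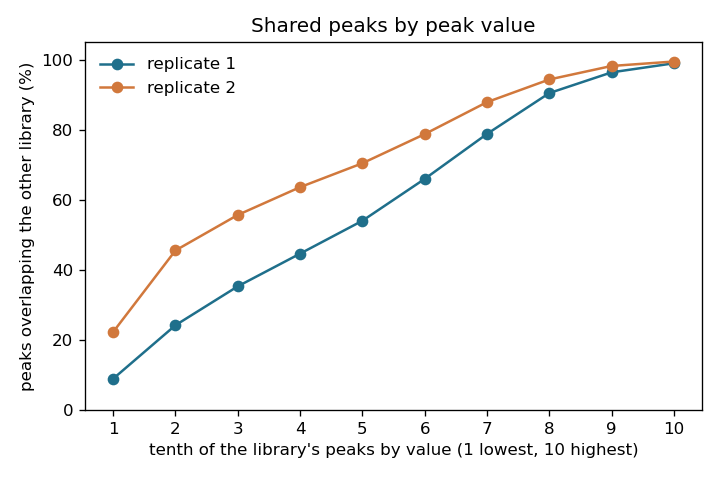
The share of each library's peaks (y axis, %) that overlap a peak of the other library, in 10 classes of equal number by peak value (x axis, 1 the weakest, 10 the strongest). Sharing climbs from 8.94% in replicate 1 and 22.3% in replicate 2 at the left to 99.0% and 99.5% at the right.

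Peaks called in a single library were weaker and narrower than shared ones. Their median value was 0.42 against 0.96 in replicate 1 and 0.41 against 0.83 in replicate 2, and their median widths were 135 and 119 bp against 274 and 229 bp. The 5 strongest of replicate 1 lay at the promoters of P4ha1 (a subunit of collagen prolyl hydroxylase, 4.02), Get4 (3.88), Tpr (a nuclear pore protein, 3.61), Stag1 (a cohesin subunit, 3.60) and Cdc27 (a subunit of the anaphase-promoting complex, 3.41). Those of the library labelled male replicate 2 lay at the promoters of Utp18 (4.00) and Actr1a (2.89), and outside promoters near Foxn3 (2.92), near Was (2.89) and near Pak3 on the X chromosome from 143483001 to 143483140 (3.82). Except for the Pak3 peak, where no base had an FDR under 0.05 in replicate 1, every base of these 10 peaks lay in a region with an FDR under 0.05 in the other library. Dense runs of weak peaks made up 16.6% of the single-library peaks of replicate 1 and 7.54% of those of replicate 2, among them runs at Lemd1 (62 peaks over 55.7 kb), Dlk1 (58) and the Hoxd genes (54) in replicate 1 and at Tcf4 (69) in the library labelled male replicate 2.

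The second question was where open chromatin lay. Promoters of protein-coding genes held many times more peaks than their length gives, since 31.3% and 34.2% of peaks (mean 32.7% ± 2.07, SD, n = 2) touched a window of 1 kb on each side of a TSS. These windows cover 3.59% of the genome, and peaks moved at random touched them in 4.46% and 4.41%. Classed by the middle base of each peak, promoters were 8.58-fold, coding exons 2.77-fold, UTRs 1.38-fold, introns 0.824-fold and intergenic sequence 0.558-fold their share of the genome. Among 21755 protein-coding genes outside the Y chromosome, 63.2% had a promoter peak in both libraries. Actb, the beta-actin gene of the cell skeleton, had promoter values of 4.14 and 4.45, and Alb, the liver's serum albumin gene, had no promoter peak and no distal peak. With the authors' stricter FDR of 0.001 the promoter share was 46.2% ± 1.83 (SD, n = 2).

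Gene groups were then compared by promoter peaks. All members of 4 lists had a promoter peak in both libraries. They were 14 of 14 pan-neuronal genes, among them Rbfox1 (an RNA splicing factor of neurons, promoter values 1.71 and 1.31), and 16 of 16 activity-regulated genes, the genes that neuronal firing switches on, with Egr1 at 4.90 and 4.24 and Fos at 2.97 and 2.25. They also were 14 of 14 GABA receptor genes and 18 of 18 housekeeping genes, such as Ppia (5.43 and 4.63). Glutamate receptor genes followed with 21 of 22, Grin2c being the exception. These 5 lists lay above random lists of genes, which averaged 63.1% to 63.3%. In the permutation test over random lists, raw p = 0.002 and adjusted p = 0.0056 for pan-neuronal genes. Raw and adjusted values were 0.0016 and 0.00498 for activity-regulated genes, 0.0026 and 0.00662 for GABA receptors, 0.001 and 0.0042 for housekeeping genes and 0.0012 and 0.0042 for glutamate receptors. The GABA receptor call was lost at the FDR of 0.001 (85.7%, adjusted permutation p = 0.0772). The calls of the other lists above random were lost against random lists matched on promoter CpG, as given below.

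Lists of other tissues and of immune and mural cells had few open promoters. In both libraries a promoter peak was found for 13 of 1093 olfactory receptor genes, 4 of 39 HOX genes (the patterning genes of the body axis), 1 of 13 liver genes and 1 of 11 germ line genes. The counts were 2 of 13 for lymphocytes, 3 of 16 for microglia (the brain's resident immune cells), 2 of 11 for mural cells, 2 of 10 for erythroid cells and 3 of 12 for skeletal muscle and heart. Some of these shares moved when 1 library was left out. HOX genes had 10.3% in both libraries, 30.8% in replicate 1 alone and 23.1% in replicate 2 alone, and in replicate 1 alone lymphocyte genes had 30.8% (15.4% in both) and microglia genes 31.25% (18.75%). In replicate 2 alone germ line genes had 18.2% (9.09% in both) and olfactory receptor genes 1.83% (1.19%). These 5 calls stood with either library left out. All 9 lay below random lists. Raw p was 0.0002, the smallest the 10000 random lists can give, and adjusted p 0.00187 for olfactory receptor, HOX and liver genes. Raw p was 0.001 for germ line, 0.0012 for lymphocyte and 0.0006 for microglia genes, with adjusted p of 0.0042 for each of these lists. Raw and adjusted p were 0.007 and 0.0163 for mural cell, 0.0152 and 0.0327 for erythroid and 0.0164 and 0.0328 for muscle and heart genes. Among microglia genes the fractalkine receptor gene Cx3cr1 and Trem2 lacked a promoter peak in both libraries, while C1qc had one in each (1.37 and 0.993).

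The other 14 lists did not pass the test with both libraries. Promoter peaks in both libraries were found for 12 of 14 dentate gyrus granule cell genes, 7 of 9 CA1 and 9 of 11 CA2 and CA3 pyramidal cell genes, 11 of 12 excitatory neuron genes and 9 of 18 inhibitory neuron genes. They were found for 10 of 11 progenitor and immature neuron genes, 10 of 11 imprinted genes and 13 of 22 genes of other brain regions. Of glial lists, 9 of 14 astrocyte, 6 of 11 oligodendrocyte precursor and 5 of 13 oligodendrocyte genes had such peaks. The other lists gave 5 of 14 endothelial, 5 of 12 ependymal and choroid plexus and 3 of 8 meningeal fibroblast genes. Prox1, which specifies dentate granule cells, had promoter values of 1.51 and 1.06, Wfs1, a CA1 marker, 2.40 and 2.53, the glutamate transporter gene Slc17a7 1.05 and 1.01, and Gad1, which makes GABA, 1.29 and 1.35. Neurod2, a transcription factor of excitatory neurons, and Olig2, one of the oligodendrocyte lineage, had a promoter peak in replicate 1 (2.12 and 0.996) and none in the library labelled male replicate 2. Promoters rich in CpG are open in most tissues. Against random lists matched on promoter CpG, the calls of activity-regulated, housekeeping, pan-neuronal, glutamate receptor, microglia, erythroid and liver genes were lost (adjusted permutation p = 0.849, 0.725, 0.136, 0.248, 0.248, 1 and 0.0622). Inhibitory neuron genes and genes of other brain regions lay below these lists (0.007 and 0.0271), but inhibitory neuron genes had 83.3% in replicate 1 alone and 50% in replicate 2 alone. Mural cell and muscle genes also lost their call when 1 library was left out, mural cell genes without replicate 1 and muscle genes without replicate 2 (adjusted permutation p = 0.0515 and 0.0774). Excitatory neuron genes gained a call without replicate 2 and progenitor and immature neuron genes without replicate 1 (0.0313 and 0.0352). With windows of 2.5 kb the erythroid, mural cell and muscle calls were lost (0.101, 0.374 and 0.248), and with autosomal genes alone the erythroid call (0.0504). At the FDR of 0.001 endothelial, inhibitory neuron, oligodendrocyte and other-region genes lay below random lists (0.0264, 0.0384, 0.0431 and 0.0416).

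Peaks away from promoters, where many enhancers lie, were ranked for each gene among the 200 genes nearest in length. Genes of excitatory neurons and activity-regulated genes stood highest. The 12 excitatory neuron genes had a mean percentile of 88.6, with 91.6 in replicate 1 and 85.5 in the library labelled male replicate 2, and 10 of them lay above the 75th. Nptx1, a synaptic pentraxin (chromosome 11 from 119538719 to 119547753), had 13.5 ± 0.71 distal peaks (SD, n = 2) where genes of its length had a median of 0, Tbr1, a transcription factor of cortical projection neurons, had 9.0 ± 2.83, and Neurod2 had 7.5 ± 0.71. The 16 activity-regulated genes had a mean percentile of 83.0, led by the immediate early genes Egr1 (5.5 ± 0.71 distal peaks, chromosome 18 from 34859823 to 34864984) and Egr3 (4 in both libraries). Fos had 3 in both and the neurotrophin gene Bdnf 2.5 ± 0.71, and Homer1 stood lowest, with 1 in both.

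CA2 and CA3 pyramidal cell genes reached a mean percentile of 70.1, with Cacng5 (6.5 ± 2.12 distal peaks, SD, n = 2) and Pcp4 (6.0 ± 1.41) on top. Astrocyte genes reached 68.4, with the glutamate transporter gene Slc1a3 (8.0 ± 1.41) and the transcription factor gene Sox9 (4.0 ± 1.41) on top and Gjb6 at 0; Gfap, the astrocyte filament gene, had 1.5 ± 0.71. Genes of other brain regions reached 64.9, with En2, a midbrain and cerebellar patterning gene (4.5 ± 2.12), and Ppp1r1b, known for striatal neurons (4.0 ± 1.41), on top. HOX genes reached 67.7, with Hoxa11 at 19 distal peaks in replicate 1 and 2 in the library labelled male replicate 2, and Hoxd8 at 14 and 2. Olfactory receptor genes lay lowest, at 34.3, and 973 of 1093 had no distal peak.

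Of the 28 lists, these 7 differed from random lists. Raw p was 0.0002, the smallest the random lists can give, and adjusted p 0.0014 for excitatory neuron, activity-regulated, HOX and olfactory receptor genes. Raw and adjusted p were 0.0084 and 0.0336 for CA2 and CA3 genes, 0.0078 and 0.0336 for astrocyte genes and 0.0042 and 0.0235 for genes of other brain regions. Genes are not replicates, and neighbouring HOX and olfactory receptor genes share peaks, which makes their p too small. The HOX call was lost without dense runs of peaks found in a single library (mean percentile 56.7, adjusted permutation p = 0.198). With gene bodies alone the HOX call and that of CA2 and CA3 genes were lost (mean percentiles 57.9 and 64.8, adjusted permutation p = 0.08 and 0.0859). Without replicate 2 the calls of CA2 and CA3, astrocyte and other-region genes were lost (adjusted permutation p = 0.13, 0.14 and 0.064). They were also lost with the stricter FDR of 0.001 (0.642, 0.374 and 0.374) and with 50 kb on each side (0.238, 0.173 and 0.246).

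**Figure D2:**
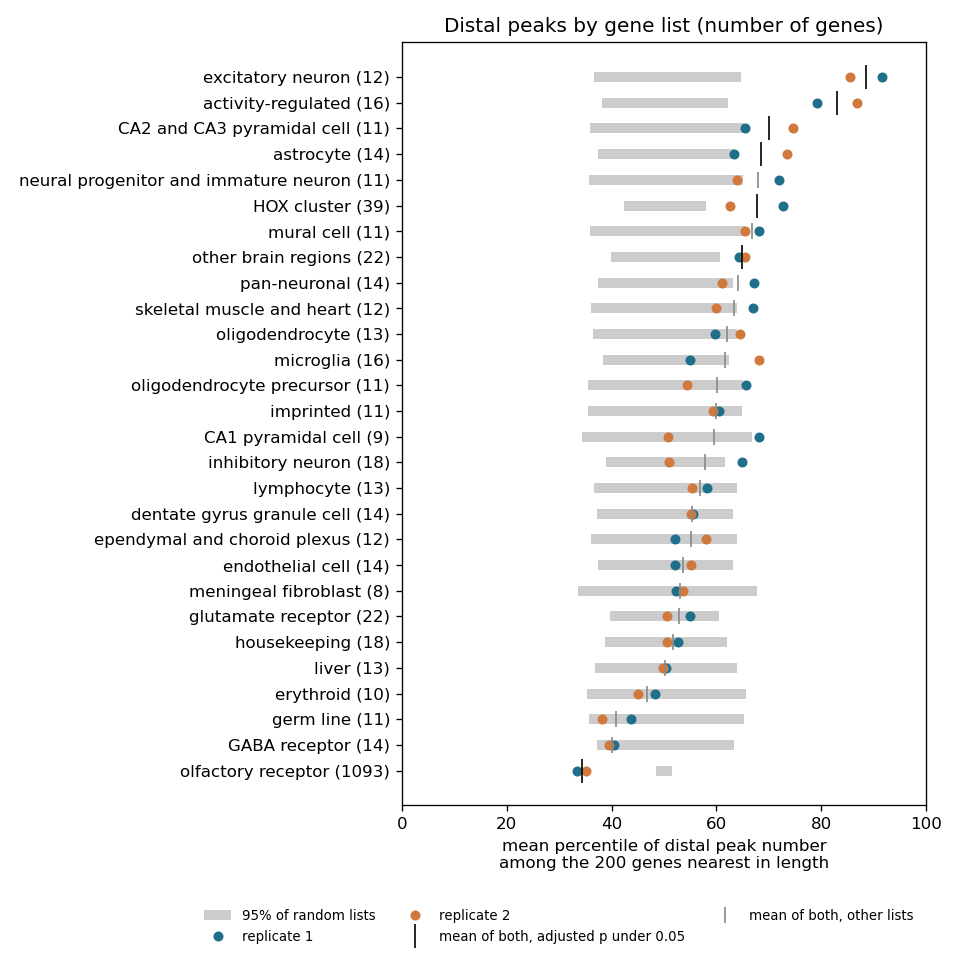
Mean percentile of distal peak number among the 200 genes nearest in length (x axis) for each of the 28 gene lists (y axis, number of genes in brackets), with coloured points for replicates 1 and 2, a tick for their mean and a grey bar for the range of 95% of random lists. The excitatory neuron (88.6) and activity-regulated lists (83.0) lie to the right of their bars and the olfactory receptor list (34.3) to the left.

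The other 21 lists did not pass the distal test in the main setting. Calls were gained by progenitor and immature neuron genes without replicate 2 (mean percentile 71.9), microglia genes without replicate 1 (68.1), pan-neuronal genes with gene bodies alone (67.6), and housekeeping (68.03) and muscle genes (70.2) with 50 kb on each side. In the main setting mean percentiles were 68.0 for progenitor and immature neuron genes, where Neurog2, a neural transcription factor gene, had 7.0 ± 4.24 distal peaks (SD, n = 2). They were 66.8 for mural cell genes, 64.1 for pan-neuronal genes, 63.4 for muscle and heart genes, 62.1 for oligodendrocyte genes, 61.6 for microglia genes, 60.05 for oligodendrocyte precursor genes, 59.9 for imprinted genes and 59.5 for CA1 genes. Inhibitory neuron genes stood at 57.9, with the neuropeptide gene Sst at 5.0 ± 1.41 distal peaks, and lymphocyte genes at 56.8, dentate granule cell genes at 55.4 and ependymal genes at 55.1. Endothelial genes stood at 53.6, meningeal fibroblast genes at 52.98, glutamate receptor genes at 52.8, housekeeping genes at 51.7, liver genes at 50.2, erythroid genes at 46.7, germ line genes at 40.9 and GABA receptor genes at 40.1. Within lists the range was wide. Prox1 had 5 distal peaks in both libraries and C1ql3 3.5 ± 0.71, while Npnt, also a granule cell marker, had 0. The AMPA receptor gene Gria1 had 27.5 ± 0.71 and the kainate receptor gene Grik5 15.5 ± 4.95, while X-linked Gria3 had 0.5 ± 0.71. Mbp, the myelin basic protein gene, had 8.5 ± 2.12, Pdgfra, the precursor marker, 8.5 ± 2.12, Sall1, a transcription factor gene listed for microglia, 7.0 ± 1.41, and the cilia gene Rsph1 17.5 ± 4.95. Cd2, a T cell surface gene, had 27 in replicate 1, where a dense run of weak peaks covers it, and 2 in the library labelled male replicate 2.

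By number alone, the genes with the most distal peaks were long. Gm20388, annotated over several Mb of chromosome 8, had 247 ± 36.8 (SD, n = 2). The growth factor receptor gene Fgfr2, annotated on chromosome 7 from 130162451 to 133123350, had 106.5 ± 4.95. These counts cover every distal peak in the annotated stretch and do not assign it to the gene. Anks1b had 76.0 ± 4.24, Cacna1d, a calcium channel gene, 56.0 ± 9.90, Asic2 55.0 ± 22.6 and Ptprn2 54.0 ± 2.83. The libraries were far apart for Kalrn (118 in replicate 1 and 29 in the library labelled male replicate 2), Clstn2 (100 and 29), Dlgap2 (44 and 85) and Tcf4 (34 and 92). A dense run called in a single library lay in each of these 4 genes. In Kalrn, Dlgap2 and Tcf4 a run lay in the library with more peaks. In Clstn2 a run of 20 peaks lay in the library labelled male replicate 2, which had fewer, so that run does not account for the gap. Runs of replicate 1 were listed by gene down to 29 peaks. Whether smaller runs of replicate 1 in Clstn2 account for the gap is therefore not known. Such runs also lay in Anks1b (43 peaks in replicate 1, and 30 and 18 at other places in the library labelled male replicate 2), Cacna1d (22) and Ptprn2 (18, both in the latter), so close totals there do not mean that the same peaks were found.

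The next question was whether the libraries differed in the markers of a cell type. Peaks of some neuronal lists weighed more in replicate 1: relative to the median gene (0.14 on the log2 scale), the summed peak value was higher than in the library labelled male replicate 2 by a median of 0.46 (1.37-fold) for excitatory neuron genes, 0.44 (1.35-fold) for CA1 genes, 0.28 for dentate granule cell genes, 0.23 for glutamate receptor genes and 0.14 for HOX genes. These 5 of 28 lists lay outside the central 95% of random lists matched on summed value, at percentiles 99.98, 99.8, 99.11, 98.71 and 99.97, where 1.4 lists would fall by chance. The other lists stayed inside. Of neuronal lists these were pan-neuronal genes (0.21, percentile 93.8), inhibitory neuron genes (0.11, 92.7), GABA receptor genes (0.058, 66.3) and CA2 and CA3 genes (-0.004, 50.3), and of glial lists oligodendrocyte genes (-0.19, percentile 9), microglia genes (-0.18, 2.63) and astrocyte genes (0.12, 85.4). This describes 2 libraries and has no p-value. The sums move with how much was called, 23.3 against 18.0 Mb, at mean autosomal peak values of 0.95 and 0.97. By the number of peaks, CA1 genes stayed outside the range and the other 4 lists did not, while inhibitory neuron genes (0.508, percentile 99.77) and progenitor and immature neuron genes (0.737, 99.65) lay outside it. Without dense runs the difference of HOX genes vanished (percentile 49.5) and excitatory neuron genes fell to 0.255 (percentile 97.85).

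Footprints were compared with the binding motifs of 24 transcription factors or families. Sites of CTCF, which organises chromatin loops, were footprinted most among the motifs that passed the test. In replicate 1, 82.0% of 3590 sites in peaks (95% exact interval 80.7 to 83.2) had their middle base in a footprint. In replicate 2 the share was 85.1% of 4386 sites (84.0 to 86.2). The motif written backwards had 3.85% and 6.67%, from 26 and 15 sites, so its shares are imprecise. The CRE, bound by CREB (47.0% and 58.1% against 10.7% and 12.3%), and the EGR motif of the immediate early factors (41.8% and 46.3% against 12.6% and 17.5%) were also footprinted more than their backward motifs. The same held for the RFX motif (25.3% and 28.7% against 8.75% and 4.69%) and the E-box of NEUROD, the neuronal differentiation factors (24.8% and 30.1% against 3.93% and 4.90%). It also held for ETS (18.6% and 21.0%), the USF E-box (17.8% and 20.2%), PU.1 (9.59% and 10.5%, in no more than 219 sites), NFY (9.91% and 7.54%) and SOX (6.17% and 6.90%). AP-1, the FOS and JUN motif, was footprinted less than its backward motif, 5.32% and 5.71% against 6.92% and 7.81%.

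These 11 motifs had adjusted p under 0.05 in Fisher's exact test, two-sided, in both libraries. In replicate 1 raw and adjusted p were 7.96e-18 and 4.77e-17 for CTCF, 3.06e-55 and 7.33e-54 for the CRE, 2.55e-13 and 1.23e-12 for NEUROD and 0.00539 and 0.00994 for AP-1. In replicate 2 they were 3.80e-11 and 1.52e-10, 2.04e-65 and 4.89e-64, 1.69e-13 and 1.01e-12, and 0.00247 and 0.0054. The NRF1 motif was footprinted in 83.9% and 84.2% of its sites, but its backward motif had 5 and 4 sites. Fisher's exact test was passed in replicate 2 alone (adjusted p = 0.328 and 0.0019). GATA (5.37% and 4.76%) and HNF4 (8.37% and 7.25%) passed in replicate 1 alone. The SP/KLF motif (33.8% and 33.7%) read backwards gives the same sites and the REST motif (28.1% and 38.7%) had no backward sites, so neither was tested this way. Against the share of peak bases in footprints both were footprinted more. YY1 (40.9% and 34.2%), NFI (35.3% and 31.7%), ZNF143 (19.1% and 27.8%), TEAD (5.46% and 4.996%), ROR (4.95% and 4.76%), MEF2 (3.81% and 7.53%), homeobox (3.21% and 3.59%) and HNF1 (0 of 4 sites and 0 of 1) did not pass. Backward sites were few for YY1 (6 and 4), NFI (4 and 4) and ZNF143 (6 and 9), so the test could hardly pass there. With the share of peak bases in footprints as reference, YY1, NFI, ZNF143 and NRF1 were footprinted more and TEAD, homeobox and GATA less. Writing a motif backwards can break its CpG, which the test does not correct for. It also changes the order of bases, so any preference of DNase I for certain sequences is not corrected for. Whether a protein was bound at these sites was not tested. In distal peaks alone the calls of AP-1, EGR, ETS, NFY, PU.1, RFX and the USF E-box were lost, and the CRE, still called, fell to 26.03% of sites from 52.5% (means of both libraries). With the whole motif required inside a footprint the calls of AP-1, NFY, PU.1, RFX and SOX were lost, and AP-1 turned to more than its backward motif (2.41% against 1.64%, means of both libraries). Against the share of peak bases in footprints (8.92%), PU.1 (10.06%) and NFY (9.91% and 7.54% against 8.57% and 9.27%) were not called and SOX (6.54%) was footprinted less.

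**Figure D3:**
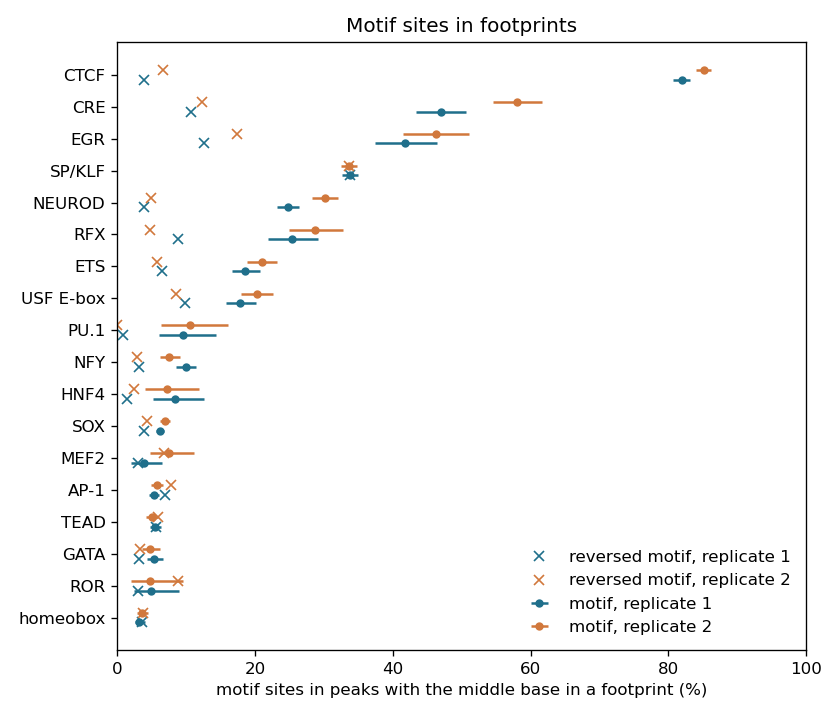
Share of motif sites in peaks whose middle base lies in a footprint (x axis, %), by motif (y axis), as points with 95% exact intervals for replicates 1 and 2. Crosses give the motif written backwards. Motifs shown have over 100 sites, and those with few backward sites in replicate 1 were left out. CTCF is shown with 26 and 15 backward sites. NRF1 (83.9% and 84.2%) and YY1 have over 100 sites but are left out, with 5 and 6 backward sites in replicate 1. CTCF lies at 82.0% and 85.1% and the CRE at 47.0% and 58.1%, each far to the right of its crosses.

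Single footprints were shared less than peaks. Of the footprints, 29.99% in replicate 1 and 39.4% in replicate 2 overlapped one of the other library by at least 1 bp, 34.0% together. Those of replicate 2 inside its peaks overlapped in 40.5%, against 16.0% ± 0.08 (SD of 100 draws) when moved to random places among all its peaks. Moved footprints left their own peak, so this chance level also carries the sharing of peaks. It is not the chance level for position inside a peak. Promoter peaks held 9.43 and 9.12 footprints per kb and distal peaks 7.11 and 7.56. Footprints had a median length of 8 and 9 bp, and 70.6% and 71.9% of peaks held at least 1.

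The last comparison set the X chromosome, of which a male carries 1 copy, against the autosomes. X-linked peaks were weaker, with a median value of 0.44 against 0.66 on autosomes in replicate 1 and 0.50 against 0.66 in the library labelled male replicate 2, and the ratio was 0.712 ± 0.074 (SD, n = 2; 0.660 and 0.765). At promoters the ratio was 0.574 ± 0.020 (0.560 and 0.588). The X chromosome held 13.19 and 12.004 peaks per Mb, against 37.1 and 31.3 on autosomes, and the autosome with the fewest, chromosome 3, held 28.8 and 24.1. No test between the libraries was made. Because the sex of the library labelled male replicate 2 is uncertain, the means over both libraries are not read as ratios of male animals.

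Genes that mark sex differed between the libraries. Replicate 1 had promoter peaks at the Y-linked genes Eif2s3y (0.890), Ddx3y (0.707), Uty (0.678) and Kdm5d (0.424). The library labelled male replicate 2 had no peak at these promoters, and no base of them had an FDR under 0.05 there, while the body of Uty held 2 peaks in it and 1 in replicate 1. It had 3 peaks at the promoter of Xist, the RNA gene that silences an X chromosome in female cells (chromosome X from 103460366 to 103483254), with a highest value of 1.01, where replicate 1 had none. Firre, an X-linked RNA gene, had 26 peaks in its body in the library labelled male replicate 2 and 1 in replicate 1. Promoter values of the X-linked genes Kdm5c (1.31 in replicate 1 and 2.14 in the library labelled male replicate 2), Kdm6a (2.34 and 3.78), Ddx3x (1.99 and 3.20) and Eif2s3x (1.37 and 2.98), which are known to stay active on the silenced X chromosome, were higher in the latter. Apart from Xist, these genes were chosen after their values were seen. The sex of the library labelled male replicate 2 is therefore uncertain, and no direction between male animals is read from X-linked genes.

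**Figure D4:**
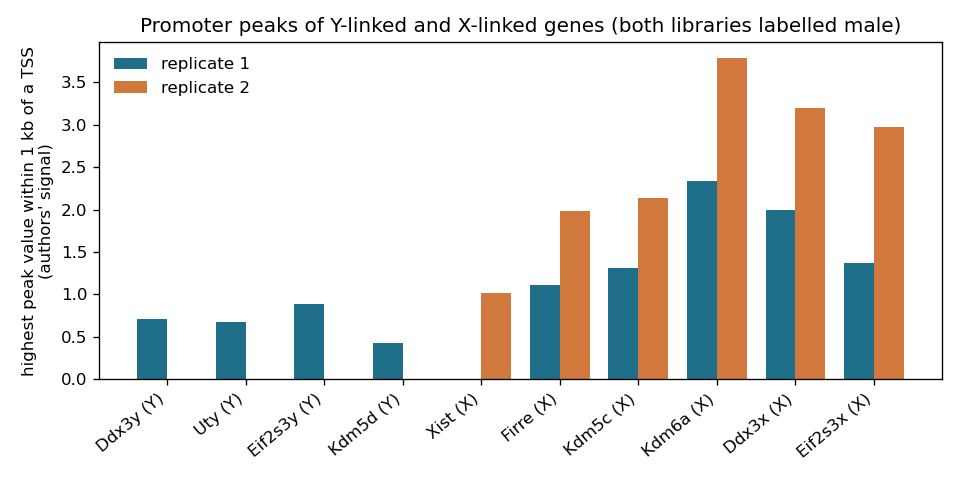
Highest peak value within 1 kb of a TSS (y axis, the authors' signal) at Y-linked and X-linked genes (x axis) in replicates 1 and 2, both labelled male. Bars at Ddx3y, Uty, Eif2s3y and Kdm5d (0.424 to 0.890) appear in replicate 1 alone and the bar at Xist (1.01) in replicate 2 alone.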

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

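Of the tests on the sex-linked genes, those of a lost Y chromosome and of peak number as the source of the peaks at Xist were chosen after the result was seen; the other tests were chosen before.

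Replicate 1 had peaks at the promoters of 4 Y-linked genes, Ddx3y, Uty, Eif2s3y and Kdm5d, a signal on a chromosome outside the list tests, while the library labelled male replicate 2 had none of them and peaks at Xist. The peaks at Xist are part of the pattern and were seen before they were set against any explanation. They argue against the loss of the Y chromosome from male cells as the whole explanation (value 1.01 against a library median of 0.65) and are not what fewer called peaks give (3 more than in replicate 1), and they decide nothing about the missing Y-linked peaks. A mislabelled sample stays open as a candidate explanation: at 7 other genes known to stay active on the silenced X chromosome (Pbdc1, Utp14a, Jpx, Ftx, 1810030O07Rik, 5530601H04Rik and Mid1) promoter values were higher in that library, by a median of 0.29 (log2) against -0.10 over 606 X-linked genes, the 97.1st percentile of random lists and just short of the bound set beforehand. Fewer called peaks stay open for the missing Y-linked peaks. Of autosomal promoter peaks of the same values, 57.0% were shared, between the bounds set beforehand. This share takes peaks singly. It does not weigh the loss at all 4 promoters together, where the library labelled male replicate 2 had no base with an FDR under 0.05. No biological explanation was tested, because the labels give a single group. Pbdc1 and 5530601H04Rik share a promoter peak and count as separate genes in the test of 7 genes.

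Signals outside the comparisons were as follows. The Y chromosome held 40 peaks in replicate 1 and 39 in the library labelled male replicate 2, with median values of 0.24 and 0.33. Of these, 11 and 19 lay at the end of Y past 90.7 Mb, which holds sequence shared with X. The source of the other Y peaks, the larger part in both libraries, was not tested. The near-equal counts are therefore not read for or against the label. Outside peaks lay 32987 footprints of replicate 1 and 19305 of replicate 2. Regions with an FDR under 0.05 that touch no peak numbered 77381 and 67065 and covered 12.02 and 10.1 Mb together with other parts of regions outside peaks.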

How the results depend on the processing

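The settings without dense runs and with autosomes alone were chosen after the results were seen. The share of shared peaks (65.2%) was 42.7% with reciprocal overlap of 50%, 68.8% with equal numbers of peaks, 68.1% at an FDR of 0.001, 47.8% over regions with an FDR under 0.05 and 68.1% without dense runs. The rho (0.921) was 0.930 with reciprocal overlap. The promoter share (32.7%) was 27.5% with windows of 500 bp, 39.5% with 2.5 kb, 37.0% with all annotated genes and 46.2% at an FDR of 0.001, which left 46079.5 peaks per library. Shared footprints (34.0%) were 23.9% with reciprocal overlap and 38.02% inside shared peaks. Of 14 promoter list calls, 9 were made with random lists matched on CpG, 7 of them among the 14, and HOX, germ line, lymphocyte and olfactory receptor genes were called under all 8 settings. Of 7 distal list calls, 4 remained at an FDR of 0.001, and excitatory neuron, activity-regulated and olfactory receptor genes were called under all 8 settings. Of 5 list differences between libraries 3 were found by the number of peaks, 1 of them among the 5, and the difference of HOX genes vanished without dense runs (-0.13, the value of lists whose median gene has no peak, percentile 49.5). Against 11 motifs, 7 were called with whole motifs (6 of the 11, and NRF1), 4 in distal peaks (all among the 11) and 18 against the share of peak bases in footprints (9 of the 11, SOX in the other direction, and 9 others), and CTCF, CRE and NEUROD under all 5 settings. AP-1 reversed with whole motifs (2.41%) and SOX (6.54%) against the share of peak bases (8.92%), a reference that ignores base make-up, where the mean of NFY (8.73%) also lay below but the libraries went opposite ways and it was not called. Except where the setting's construction shows it, the cause was not tested.

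Leaving out each library gave promoter shares of 31.3% to 34.2%, X to autosome ratios of 0.660 to 0.765, 79144 to 93545 peaks, 14 promoter list calls either way, 5 to 8 distal list calls and 12 to 13 motif calls. Of the summary values under alternatives, 29 stayed within the spread, interval or 1.5 times the count and 19 did not. Of single lists and motifs 550 kept their side of the threshold, 42 lost a call without a change of sign and 28 gained a call. Of those called in the main setting, 4 changed sign (AP-1, SOX, NFY and HOX genes, above). Of these, SOX alone was still called where its sign changed, and the others lost their call there. Where neither setting gave a call, direction was not compared. Astrocyte promoter peaks, for example, lay above random lists (64.3% against 63.0%) and below those matched on CpG (68.1%). No paired analysis was possible because the labels give a single group. The depth of the libraries is not known, so weak peaks missing from a library were not detectable at its calling threshold and are not shown to be closed.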

Other observations

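All tests of dense runs in this part were chosen after the result was seen; the 2 tests of the strongest shared peaks were chosen before.

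Sequence motifs in distal peaks, against flanks 1 kb away from each peak, add to the account of footprints. Sites of CTCF were 64.8 ± 22.2 times (SD, n = 2) as dense in distal peaks as in flanks, against 2.16 times for the motif written backwards. RFX sites were 5.83 ± 0.87 times as dense (1.26 backwards), NEUROD sites 3.94 ± 0.43 times (1.72) and CRE sites 2.64 ± 0.30 times (1.51). EGR sites were 10.3 ± 2.08 times as dense, but so was the backward motif (10.96). MEF2 sites were as dense as in flanks (1.04 ± 0.18) while the backward motif was sparser (0.386), and homeobox (0.450 ± 0.024) and GATA sites (0.534 ± 0.019) were sparser in both forms (0.375 and 0.585). Distal peaks were richer in G and C than flanks (53.2% and 52.8% against 44.5% and 44.4%), so folds were read against the backward motif. Distal peaks also held more CpG, 23.54 per kb in replicate 1 and 23.97 in replicate 2, against 9.98 and 9.93 in flanks. Writing a motif backwards can break its CpG, so the backward motif does not correct for this difference. The CRE fold was not told apart from it.

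Among imprinted genes outside the protein-coding list, which are expressed from the copy of a single parent, Meg3 had 6 promoter peaks in replicate 1 and 5 in the library labelled male replicate 2 (highest values 1.12 and 1.16), and H19 had none in either. Airn had 63 peaks in its body in replicate 1 and 9 in the library labelled male replicate 2, and Kcnq1ot1 2 and 30. A dense run of 53 weak peaks (median value 0.16) called in replicate 1 lay in Airn and one of 28 (0.12) called in the library labelled male replicate 2 lay in Kcnq1ot1, so these counts are not read as a difference at imprinted genes. Alleles of the hybrid's parents were not analysed here.

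Dense runs of peaks called in a single library, such as those at Lemd1, Dlk1, Kalrn and the Hoxd genes in replicate 1 and at Tcf4 and Dlgap2 in the library labelled male replicate 2, numbered 308 and 89. Depth alone is argued against, since 22.4% of the runs lay in the library with fewer, and so are shifted calls, since the runs held at most 13.8 peaks of the other library per 100 of their own. Peaks split from a wider one of the other library would overlap it, and runs leave out such peaks by definition. A lower local threshold of the authors' peak calling is a candidate explanation. The median value in runs (0.25 and 0.18) lay at the 5.33rd percentile or lower of the same library's peaks outside runs (medians 0.69 and 0.66). Part of this low rank follows from how runs were chosen. They hold single-library peaks alone (medians of all such peaks 0.42 and 0.41), while peaks outside runs include the stronger shared ones. No biological explanation was tested, and the runs were found and tested on the same data.

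The strongest shared peaks, led by those at CT010467.1 and Lars2, lay partly at repeated sequence. The search for copies could not count those that the reference lacks. Another near-identical copy in the reference was found for 18.3% of the 60 strongest, against 1.33% of 300 random shared peaks. That was more often than by chance but under the share set beforehand for naming reads shared between copies as the source of these 60 peaks. Their median GC share was 7.17 percentage points above that of random shared peaks, between the bounds set beforehand, but 8 of the 10 strongest, with 47.1% to 53.6%, lay below the random median of 55.6%. Unusual base make-up is therefore left open for the 60 peaks as a set, and high GC does not describe the peaks at CT010467.1 and Lars2. Neither explanation can be told apart from the other or from open chromatin at these places by these tests, and no biological explanation was tested.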
